A study of Mus musculus with 2 samples.

How the data were processed

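Single-cell RNA sequencing was read from 2 libraries of cells taken out of scaffolds that filled a cranial bone defect in mice. Per the labels, female Balb/c mice aged 6 weeks received a circular skull defect of 3.5 mm that was filled with a cell-free scaffold of the same diameter, either Gel100 or Gel50_CS50. Per the labels' protocols, the scaffolds of 5 mice per group were collected at week 1 and pooled. Cells were released with an enzyme mixture that held Liberase, chondroitinase and hyaluronidase, red blood cells were lysed, and viable cells were sorted by flow cytometry before about 10000 of them were loaded on a 10x Chromium controller with the 3' kit. What the scaffold names stand for is not given in the sources used here. Each group is therefore 1 library from 1 pool of 5 mice, and there are no replicates. The mice in a pool were not told apart.

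The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization, written by Cell Ranger 6.0.2 per the file headers. The submitters' processing notes name Cell Ranger and the mouse genome build mm10. The annotation release behind the gene identifiers is not given in the sources used here. The 2 matrices share 32285 genes, of which 38 symbols stand on more than 1 identifier and were kept apart by identifier. Of the identifiers, 99.8% were found in the GENCODE vM21 annotation of mm10, which gave the coordinates printed with genes. The counting of reads shared by near-identical genes is not stated, so the levels of Stfa3, Ifit1bl1, Ifit3b, Ly6a, Ly6c1, Ly6c2 and Hist1h2ap are uncertain. The Gel100 matrix held 7845 barcodes and 108847835 UMIs, and the Gel50_CS50 matrix held 7515 barcodes and 150311308 UMIs. The lowest barcode had 500 and 503 UMIs, so the matrices had been filtered before deposit. The 24 barcode sequences present in both libraries were kept in both.

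The grouping, the cell filter, the clustering settings, the cell type markers, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Barcodes were kept with at least 200 genes, at least 500 UMIs and under 20% mitochondrial counts, which removed 65 barcodes of the Gel100 and 117 of the Gel50_CS50 library. Scrublet, run per library in scanpy 1.11.5 at an expected doublet rate of 0.06, called 226 (2.90%) and 204 (2.76%) doublets, and these were removed. This left 7554 and 7194 cells. Counts were scaled to 10000 per cell and log-transformed. Mitochondrial genes were left out, and 3000 variable genes gave 30 principal components. A graph of shared neighbours (15 per cell) was clustered with leidenalg 0.10.2 at resolution 1.0, both libraries together and with no integration. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

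Each cluster took the class whose fixed markers had the highest mean log2 level over the median cluster. It stayed unnamed where that score was under 1.5, where it led the next class by under 0.5, or where fewer than 3 of the markers were detected in at least 10% of its cells. These limits, and a limit of 1000 on the median UMI count of a named cluster, were set after the data were seen. Classes are called by their cell type below and rest on markers alone, so each name means a cell like that type. The 10 genes with the highest fold per cluster were searched for markers of other classes. Here a gene on a fixed list of a class counted as that class's own marker, a reading also adopted after the data were seen. On the fixed markers alone, cluster 6 (Ctsk and Atp6v0d2) and cluster 11 (Arg1) would have held more markers of other classes than of macrophages, so the macrophage results were also computed without them. Macrophage and monocyte clusters were joined in a class, as were T, gamma-delta T and NK cell clusters. The clusters of the stromal class all scored highest for the fibroblast or mesenchymal markers.

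Shares are percentages of kept cells with exact Clopper-Pearson 95% intervals, and differences of shares have Newcombe intervals. A floor of 3 counts is a share of 0.0397% in the Gel100 and 0.0417% in the Gel50_CS50 library. The exact interval of a share of 0 reaches further, to 0.0488% in Gel100. Within a class, counts were summed over the cells of a library and scaled to a total of 1e6, which gives CPM. The log2 ratio of Gel50_CS50 over Gel100 has an exact conditional binomial 95% interval. All these intervals cover counting error only, not the spread between mice or pools. No test between the groups was run, and no p-value or count of changed genes is given, since cells are not replicates. Genes were measured in a class with a mean of at least 20 CPM over both libraries. Named genes were the 10 highest and 10 lowest ratios per main class (5 and 5 in the other classes with at least 100 cells in both libraries) among genes with a mean of at least 50 CPM and an interval wholly beyond 1.5-fold. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor segment genes and unnamed gene models were left out. Up to 4 measured members of each list with the largest absolute ratio were added, and ligand and receptor pairs whose ligand differed by more than 1.5-fold at 20 CPM or more.

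For each fixed gene list, the median log2 ratio of the measured members was set among 10000 random lists of the same size, drawn within 50 ranks of mean expression, and the resulting percentile describes these libraries only. Lists with fewer than 3 measured members were given no median. The lists for sprouting and activated endothelium were not used, because fewer than 100 endothelial cells were kept in each library. Mx1, a member of the interferon list, was not analysed here. Some genes that the rule for named genes picks are not reported here.

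Alternatives were a stricter cell filter (at least 500 genes and 1000 UMIs, under 10% mitochondrial counts), doublet calls kept, Leiden resolutions 0.5 and 2.0, 50 principal components, and each library clustered alone. Gene values were also computed with TMM factors from edgeR 4.0.16 (R 4.3.3), with median-of-ratios size factors of the DESeq2 type, and with each cell weighted equally. Further alternatives weighted the clusters of a class equally in both libraries (clusters with at least 20 cells in each), thinned each cell to 3000 UMIs, and changed the limit on mean CPM to none or 100. Alternatives chosen after seeing the data gave low-UMI clusters to their best class, kept cells with at least 3000 UMIs only, left out clusters 6 and 11, and added mixed cluster 18 to the neutrophils. The ratio, interval and list steps were tested on simulated data, with 200 genes changed per class, 100 by 2-fold and 100 by 1.5-fold. Counts were independent Poisson draws per gene from the real means and totals. The intervals assume this same model, so coverage near 95% checks the computation only. Variation between cells was not simulated. In the macrophage class, 95.3% of the 6099 simulated intervals held the true ratio, and 100% of the genes changed 2-fold, 18% of those changed 1.5-fold and 0% of the unchanged ones lay wholly beyond 1.5-fold. In the stromal class (6944 genes) the intervals held the true ratio in 95.4% and in the T/NK class (6493 genes) in 95.3%. In both, 100% of the genes changed 2-fold and 0% of the unchanged ones lay wholly beyond 1.5-fold, as did 2% (stromal) and 5% (T/NK) of those changed 1.5-fold. Of 100 unchanged lists drawn per class, 3% in the macrophage, 8% in the stromal and 2% in the T/NK class lay outside the central 95% of their random lists, and a list raised 1.5-fold lay at percentile 100 in each.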

Results

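Cells recovered at week 1 from 2 kinds of scaffold in a mouse skull defect were profiled by droplet single-cell RNA sequencing, with 1 library of 5 pooled mice for Gel100 and 1 for Gel50_CS50. The series title frames the comparison as one of scaffold composition and of crosstalk between immune and stem cells. After filtering, the Gel100 library held 7554 cells with a median of 12726 UMIs and 3504 genes, and the Gel50_CS50 library held 7194 cells with a median of 16485.5 UMIs and 4030 genes. Cells under 1000 UMIs made up 11.2% of the Gel100 and 1.40% of the Gel50_CS50 library. The median share of mitochondrial counts was 1.2% and 2.0%. There are no replicates, so every difference below is a difference between 2 libraries, without a test or a replicate check. Intervals are 95% and cover counting error only.

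Which cell types made up each library was read from the class shares. Neutrophils, the granulocytes that arrive early at a wound, made up 19.5% of the Gel50_CS50 library (18.6 to 20.4%, 1402 cells) and 8.12% of the Gel100 library (7.51 to 8.75%, 613 cells). Stromal cells, identified by collagen and mesenchymal markers, made up 9.08% (8.42 to 9.76%, 653 cells) and 3.18% (2.79 to 3.60%, 240 cells), a ratio of 2.86. T and NK cells were less frequent in the Gel50_CS50 library, at 6.74% (6.17 to 7.35%, 485 cells) against 12.4% (11.6 to 13.1%, 934 cells). Macrophages and monocytes were the most frequent class in both, at 53.3% (52.2 to 54.5%, 3837 cells) in Gel50_CS50 and 51.7% (50.6 to 52.9%, 3907 cells) in Gel100.

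The difference was 11.4 percentage points for neutrophils (10.3 to 12.5), 5.90 for stromal cells (5.13 to 6.68) and -5.62 for T and NK cells (-6.57 to -4.68). Plasmacytoid dendritic cells, which sense nucleic acids and make type I interferon, made up 3.54% of the Gel50_CS50 and 5.40% of the Gel100 library. Conventional dendritic cells, which present antigen to T cells, made up 2.45% and 3.55%. Their share depended on the clustering, at 5.89% and 6.24% with 50 principal components (difference -0.34 points, -1.11 to 0.43) and 2.502% and 6.301% with each library clustered alone. Among the rarer classes, pericytes or smooth muscle cells made up 0.723% (52 cells) and 0.371% (28 cells), mast cells or basophils 0.5004% (36 cells) and 0.225% (17 cells), and endothelial cells 0.764% (55 cells) and 0.821% (62 cells). Group 2 innate lymphoid cells numbered 16 and 7, and B cells 11 and 10. Within the T/NK class of Gel50_CS50, 43.5% of cells were NK cells (39.0 to 48.0%), 41.4% T cells and 15.1% gamma-delta T cells (11.99 to 18.6%). In Gel100 these were 50.1% (46.9 to 53.4%), 39.6% and 10.3% (8.40 to 12.4%). Clusters left unnamed for their low UMI counts held 13.03% of Gel100 and 1.43% of Gel50_CS50, most of them closest to macrophages, and a mixed cluster held 1.01% and 1.57%. The depth gap and the sort for viable cells can both set these shares. For macrophages, the difference of 1.61 points (0.00284 to 3.23) became -7.42 when the low-UMI clusters were given to their closest class, and -5.01 among cells with at least 3000 UMIs.

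**Figure D1:**
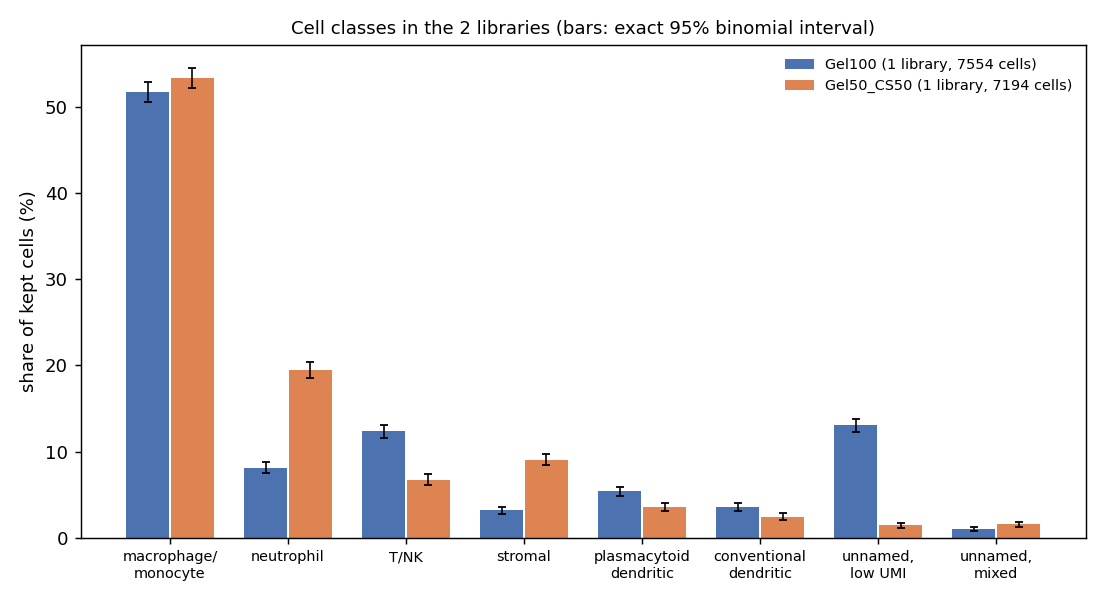
Share of kept cells (%, vertical axis) in each cell class for the Gel100 (7554 cells) and Gel50_CS50 (7194 cells) libraries, with exact 95% binomial intervals for counting error. Neutrophils stood at 8.12% and 19.5%, stromal cells at 3.18% and 9.08%, T and NK cells at 12.4% and 6.74%, and unnamed low-UMI clusters at 13.03% and 1.43%.

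How macrophages and monocytes differed between the scaffolds was read from counts summed over 3907 cells in Gel100 and 3837 in Gel50_CS50. Genes induced by interferons, which mark antiviral and inflammatory signalling, were lower in the Gel50_CS50 library: 14 of the 15 measured genes of the interferon list lay below 1/1.5 of their Gel100 level. The antiviral enzyme Rsad2 stood at 971.5 CPM in Gel100 and 375.6 in Gel50_CS50, a log2 ratio of -1.37 (-1.39 to -1.35), and Ifit2, an inhibitor of translation, at 541.9 and 186.3. Arg1, the arginase that marks alternatively activated macrophages, was higher in Gel50_CS50, at 422.2 CPM against 67.6 (2.64, 2.60 to 2.69). Fn1, which encodes the matrix protein fibronectin, stood at 1157 against 342.3 CPM (1.76, 1.74 to 1.78), and the mannose receptor Mrc1 at 522.5 against 263.3 (0.99, 0.96 to 1.01).

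On mm10, Rsad2 (ENSMUSG00000020641) lies on chromosome 12 at 26442746 to 26456452 and Arg1 (ENSMUSG00000019987) on chromosome 10 at 24915221 to 24927484. Fn1 lies on chromosome 1 at 71585520 to 71653200, and Mrc1 on chromosome 2 at 14229392 to 14332057. Over the 6128 measured genes of the class the median log2 ratio was -0.01, and the central 95% of genes lay between -0.83 and 0.57. The interferon list had a median of -1.15 and lay at percentile 0 of the random lists. Cmpk2 (162.6 and 54.1 CPM) and the guanylate-binding protein genes Gbp2 (198.8 and 69.3 CPM) and Gbp6 (79.2 and 25.1 CPM) were among its lowest or the lowest of all genes. Leading genes lower in Gel50_CS50 also held Ccl5, a chemokine for T cells (1358 and 433 CPM, -1.65), the surface receptors Slamf9 (-1.71) and Slamf7 (-1.58), and AW112010 (-1.69). Ifit1bl1 (-2.57), Ifit3b (-1.68), Ly6a (-1.83) and Ly6c1 (-1.83) were lower too, but have close copies.

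Leading genes higher in Gel50_CS50 held the neutrophil-attracting chemokine Cxcl3 (90.4 against 22.4 CPM, 2.01), the cystine transporter Slc7a11 (1.69), the coagulation factor gene F13a1 (489.7 against 165.3 CPM, 1.57), Cav1 (1.90), Clmp (1.77), Ifitm1 (1.44) and Stfa3 (151.6 against 5.19 CPM, 4.87), which has close copies. S100a8 was at 114.6 against 25.5 CPM (2.17). It is a neutrophil marker at 19500 CPM in the neutrophils of the Gel50_CS50 library, and these were 2.40 times as frequent there. Some clusters differed in their share of the class: cluster 0 held 39.5% of it in Gel100 and 5.94% in Gel50_CS50, whereas clusters 2 and 11 held 7.81% and 1.48% in Gel100 and 19.1% and 15.7% in Gel50_CS50. Leading genes of cluster 0 included Ifit1bl1, Slamf7 and Ccl12, and those of cluster 2 Mrc1, Gas6 and C1qa. Ratios over the whole class therefore do not by themselves show a difference between cells of the same cluster. With both libraries weighted to the same clusters, the interferon median was -0.34, Arg1 stood at 1.69, Fn1 at 1.09, Cxcl3 at 0.25, Cav1 at 0.66, Clmp at 0.65, Stfa3 at 1.47, Slc7a11 at 0.94, Ccl5 at -0.60, Cmpk2 at -0.47, Slamf7 at -0.68, Gbp6 at -0.89, AW112010 at -0.78, Ifit1bl1 at -0.92, Ifit3b at -0.37, Ly6a at -1.10 and Ly6c1 at -0.87. Clusters 6 and 11 scored highest for macrophage markers (3.58 and 2.35, against 2.04 and 1.01 for the next class). Their leading genes also held fixed markers of other classes, Ctsk and Atp6v0d2 in cluster 6 and Arg1 in cluster 11. Without both clusters, Arg1 stood at 1.29, Stfa3 at 1.87, S100a8 at 0.96, Cxcl3 at 1.36, Cav1 at 1.01 and Clmp at 1.16. Arg1, Stfa3, Cxcl3 and Cav1 were leading genes of cluster 11, so their ratios were bound to fall without it.

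Of 9 measured alternative activation genes, 3 were above 1.5-fold and 1 below 1/1.5, with a median of 0.31 (percentile 99.9). Beside Arg1 and Mrc1, the chemokine gene Ccl24 was higher (61.8 against 35.5 CPM) and Pparg, a lipid-sensing nuclear receptor, lower (46.0 against 89.1 CPM). The list of resident-type and complement genes had 5 of 12 above 1.5-fold, with a median of 0.36 (percentile 100). Its members included Pf4 (753.3 against 303.9 CPM) and the TAM receptor ligand Gas6 (44.7 against 20.7 CPM). That median was -0.12 among genes with a mean of at least 100 CPM. Lipid-associated and foreign-body type genes had 3 of 16 above 1.5-fold, with a median of 0.27 (percentile 99.98). They included osteopontin, Spp1 (1148 against 607.5 CPM), the proton pump subunit Atp6v0d2 (43.4 against 19.3 CPM) and Cd9 (149.5 against 91.1 CPM), and the median without clusters 6 and 11 was -0.048. Repair growth factors had 3 of 11 above 1.5-fold and a median of 0.30 (percentile 99.98), among them the EGF receptor ligand Areg (60.9 against 19.4 CPM) and Pdgfc (45.5 against 29.9 CPM).

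Inflammatory genes went both ways. Of 17 pro-inflammatory activation genes, 3 were above and 3 below, with a median of -0.06 (percentile 7.67). The interleukin gene Il1a (168.7 against 70.8 CPM) and the acute-phase gene Saa3 (2020 against 875.3 CPM) were higher, and the T cell chemokine Cxcl9 was lower (26.4 against 53.6 CPM). Of 16 chemokine genes, 4 were above and 6 below, with a median of -0.23 (percentile 0.12). Ccl2, which recruits monocytes, stood at 321.4 against 690.6 CPM (-1.10) and Ccl12 at 110.6 against 233.7 CPM. The circulating monocyte list also split, with 3 of 9 above and 3 below and a median of -0.22 (percentile 0.92). The monocyte marker Ly6c2 (473.5 against 1362 CPM) was lower, and Hp (247 against 98.9 CPM) and Vcan (241.7 against 119.9 CPM) higher. That median was 0.39 at a mean of at least 100 CPM and 0.033 with the same cluster weights.

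Lysosome and phagocytosis genes had a median of -0.12 (percentile 0.75) with 1 of 18 below 1/1.5, the receptor kinase Axl (45.4 against 79.7 CPM). MHC class II presentation genes had a median of 0.16 (percentile 90.8) with 0 of 8 beyond 1.5-fold, and the median was 0.50 without clusters 6 and 11. Unfolded protein response genes had 0.19 (percentile 99.3) with 0 of 9 beyond. For sulfated glycosaminoglycan breakdown and binding the median was 0.16 (percentile 98.7) with 0 of 11 beyond, the hyaluronan receptor Cd44 being highest (1628 against 1158 CPM). Immediate-early and heat-shock genes had a median of 0.18 (percentile 98.0) with 0 of 15 beyond, and Egr1 stood at 1044 against 755.3 CPM. Glycolysis and hypoxia genes had a median of 0.13 (percentile 94.98) with 1 of 14 above, the oxygen sensor Egln3 (35.3 against 15.6 CPM), and the median was -0.028 with the same cluster weights and -0.079 without clusters 6 and 11. Nuclear oxidative phosphorylation genes had 0.08 (percentile 89.5) with 0 of 15 beyond, and cholesterol synthesis genes -0.07 (percentile 34.6) with 0 of 3. Only 2 cell cycle genes were measured, Mki67 (45.8 against 24.1 CPM) and Hmgb2 (119.4 against 124.1 CPM).

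**Figure D2:**
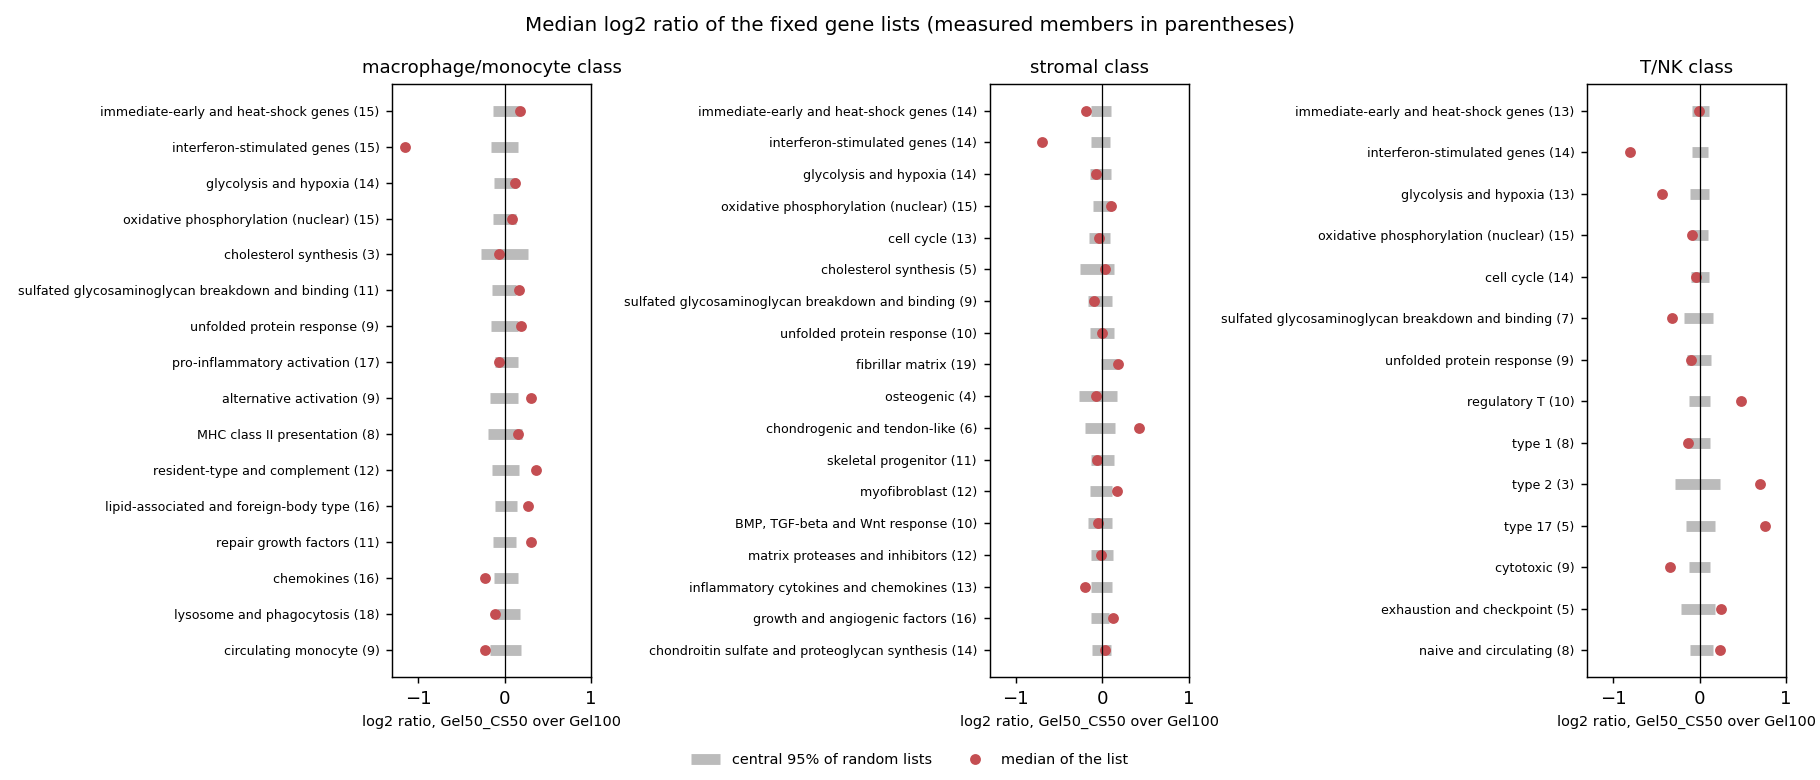
Median log2 ratio of Gel50_CS50 over Gel100 (horizontal axis) for each fixed gene list in the macrophage/monocyte, stromal and T/NK classes (red points), over the central 95% of 10000 random lists matched on expression (grey bars). Interferon-stimulated genes lay lowest in each class, at -1.15, -0.70 and -0.81, and the type 17 list lay highest in the T/NK class, at 0.76.

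How the stromal cells differed was read from 240 cells in Gel100 and 653 in Gel50_CS50, with medians of 46443 and 53577 UMIs per cell. Mmp13, the collagenase of bone remodelling, was higher in the Gel50_CS50 library, at 125.9 against 29.7 CPM (log2 ratio 2.08, 1.92 to 2.25, and 1.42 with cells thinned to 3000 UMIs). Cxcl5, a chemokine for neutrophils, stood at 433.2 against 182.6 CPM (log2 interval 1.18 to 1.31). Lower were the chemokine genes Cxcl9, at 46.9 against 229.8 CPM (-2.29, -2.38 to -2.20), Cxcl10 at 87.3 against 244.1 CPM (-1.48, and -2.17 with each cell weighted equally) and Ccl2 at 385.1 against 807.8 CPM (-1.07). The hyaluronan receptor Cd44 stood at 716.8 against 1669 CPM (-1.22, -1.25 to -1.19). Of 14 measured interferon-stimulated genes 9 lay below 1/1.5 of their Gel100 level, with a median of -0.70 (percentile 0), including Rsad2 (35.5 against 85.8 CPM) and the transcription factor Irf7 (130.9 against 263 CPM). That median was -1.06 with each cell weighted equally.

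Mmp13 (ENSMUSG00000050578) lies on chromosome 9 at 7272514 to 7283331, Cxcl9 (ENSMUSG00000029417) on chromosome 5 at 92321347 to 92328079 and Cd44 (ENSMUSG00000005087) on chromosome 2 at 102811141 to 102901665. Over 6996 measured genes the median log2 ratio was -0.02, and the central 95% of genes lay between -0.59 and 0.43. Clusters 13, 17 and 26 held the class in much the same shares, with cluster 13 holding 63.3% in Gel100 and 59.4% in Gel50_CS50. Other leading genes higher in Gel50_CS50 were Brinp3 (1.31), the ankyrin gene Ank3 (1.29, and 0.64 with each cell weighted equally), the matrix gene Svep1 (1.28), Kif26b (1.20), Rnf150 (1.14), Cyp7b1 (1.08, and 0.46 with cells thinned to 3000 UMIs), Thsd7a (1.07) and the secreted peroxidase gene Gpx3 (1.06). Lower were Serpinb2, a plasminogen activator inhibitor (50.8 against 177.2 CPM, -1.80), the growth factor gene Igf2 (28.4 against 94.7 CPM, -1.74), Dlk1, a Notch-family inhibitor of adipogenesis (-1.55), Apod (-1.40), the matricellular gene Ccn3 (193 against 489.7 CPM, -1.34) and Ctnnd2 (-1.28). Hist1h2ap (-1.55) has close copies. Ccl5 was lower as well (-2.08, and -3.55 with each cell weighted equally), and stands at 2782 CPM in the conventional dendritic cells of the Gel100 library against 92.1 in these stromal cells.

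Matrix and cartilage genes lay above the middle of the random lists. The 19 fibrillar matrix genes had a median of 0.18 (percentile 99.2) with 0 beyond 1.5-fold. Col12a1 stood at 1172 against 788.4 CPM and Col6a1 at 1121 against 850.3, and fibrillin, Fbn1, lower at 1735 against 2268 CPM. Of 6 chondrogenic and tendon-like genes 2 were above 1.5-fold, with a median of 0.43 (percentile 100), namely Matn4 (36.4 against 18.7 CPM) and Col11a1 (583.2 against 313.8 CPM). Of 12 myofibroblast genes 2 were above, with a median of 0.18 (percentile 99.9), namely the collagen receptor Itga11 (50.8 against 29.4 CPM) and the myosin light chain Myl9 (88.0 against 53.8 CPM). Of the osteogenic list only 4 genes were measured, with a median of -0.07 (percentile 29.0) and 0 beyond 1.5-fold, and that median was -0.25 with each cell weighted equally and 0.28 with no limit on mean CPM. The bone master regulator Runx2 stood at 258.7 against 213.7 CPM.

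Signalling and remodelling lists split. Of 12 matrix protease and inhibitor genes, 2 were above and 2 below, with a median of -0.01 (percentile 41.6), as Mmp3 was higher (43.5 against 24.3 CPM) and the inhibitor Timp3 lower (144.3 against 280.4 CPM). Inflammatory cytokines and chemokines had 2 of 13 above and 4 below, with a median of -0.20 (percentile 0.14). Tnfrsf11b, the osteoprotegerin gene that restrains osteoclast formation, stood at 42.2 against 84.0 CPM. Growth and angiogenic factors had 2 of 16 above and 4 below, with a median of 0.12 (percentile 99.8) that was -0.030 with no limit on mean CPM. Among them Angpt1 was higher (159.5 against 88.0 CPM), and Igf1 (71.5 against 130.2 CPM) and Inhba (62.1 against 123.1 CPM) were lower. In the BMP, TGF-beta and Wnt response list, 1 of 10 was above and 2 below, with a median of -0.05 (percentile 31.4). There the Wnt modulator Sfrp1 stood at 38.5 against 18.1 CPM and the Wnt inhibitor Dkk2 at 121.3 against 276.9. Skeletal progenitor genes had 1 of 11 above and 2 below, with a median of -0.06 (percentile 13.4). Among these, the niche chemokine Cxcl12 stood at 239.4 against 144 CPM and Thy1 at 180.2 against 325.1.

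Chondroitin sulfate and proteoglycan synthesis genes had a median of 0.03 (percentile 71.9) with 1 of 14 above 1.5-fold, the chain-initiating transferase Csgalnact1 (150.8 against 95.1 CPM), and a median of 0.20 with each cell weighted equally. Sulfated glycosaminoglycan breakdown and binding genes had a median of -0.10 (percentile 12.99) with 1 of 9 below, Cd44. The remaining stromal medians were -0.19 for immediate-early and heat-shock genes (percentile 0.27, 0 of 14 beyond), -0.07 for glycolysis and hypoxia (percentile 20.6, 1 of 14 below, the hexokinase Hk2 at 87.4 against 135 CPM) and 0.10 for oxidative phosphorylation (percentile 96.3, 0 of 15 beyond). They were -0.04 for the cell cycle (percentile 44, 0 of 13 beyond), 0.03 for cholesterol synthesis (percentile 80.2, 1 of 5 above, Fdps at 34.8 against 19.4 CPM) and 0.00126 for the unfolded protein response (percentile 49.2, 0 of 10 beyond).

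How T and NK cells differed was read from 934 cells in Gel100 and 485 in Gel50_CS50, with medians of 9174 and 9912 UMIs. Relative to all counts of the class, genes of regulatory T cells were higher in the Gel50_CS50 library, with 4 of 10 above 1.5-fold. Foxp3, the factor that defines this lineage, stood at 62.6 against 32.1 CPM (log2 ratio 0.96, 0.74 to 1.18), and Il2ra, a subunit of the interleukin-2 receptor, at 624.6 against 352.7. Of 5 type 17 genes, 4 were above 1.5-fold, with the cytokine gene Il17a at 48.6 against 25.9 CPM (0.91, 0.66 to 1.16). Of 9 cytotoxic genes 2 lay below 1/1.5, as granzyme B, Gzmb, stood at 505 against 1090 CPM (-1.11, -1.17 to -1.05) and perforin, Prf1, at 244.9 against 472.3 CPM (-0.95). The cytokine gene Ifng stood at 59.5 against 117.1 CPM (-0.98, -1.16 to -0.80).

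Foxp3 (ENSMUSG00000039521) lies on chromosome X at 7573644 to 7595245, Il17a on chromosome 1 at 20730905 to 20734496 and Gzmb (ENSMUSG00000015437) on chromosome 14 at 56258838 to 56262260. The regulatory T list had a median of 0.48 (percentile 100) and the type 17 list 0.76 (percentile 100), the latter also with Cd163l1 at 216.7 against 95.8 CPM and the receptor Il23r at 173.2 against 106.7. Cluster 8 held 50.1% of the class in Gel100 and 43.5% in Gel50_CS50, cluster 20 held 10.3% and 15.1%, and cluster 23 held 7.60% and 11.7%. In cells, cluster 20 held 96 and 73 and cluster 23 held 71 and 57. Both were thus larger in Gel50_CS50 only as a share of the class. With both libraries weighted to the same clusters, the regulatory T median was 0.14 and the type 17 median 0.034, and with each cell weighted equally the latter was 0.45. Of 3 type 2 genes 2 were above 1.5-fold, with a median of 0.70 (percentile 99.9), among them the interleukin-33 receptor Il1rl1 (70.8 against 22.1 CPM), and the median was 0.21 with the same cluster weights. The cytotoxic list had a median of -0.35 (percentile 0) with 2 of 9 below 1/1.5, and the type 1 list -0.14 (percentile 1.51) with 2 of 8 below, Ifng and the chemokine gene Ccl4 (250.5 against 542.7 CPM).

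Interferon-stimulated genes had a median of -0.81 in the T/NK class (percentile 0), with 8 of 14 below 1/1.5, among them Ifi44 (120.5 against 284.4 CPM) and Ifit3 (48.6 against 92.2 CPM). Genes of macrophages as a share of their level in macrophages stood at 3.09% in the T/NK cells of Gel100 and 1.76% in those of Gel50_CS50. Glycolysis and hypoxia genes had a median of -0.43 (percentile 0) with 3 of 13 below, including the enzymes Tpi1 (114.9 against 215 CPM) and Eno1 (218.7 against 370.7 CPM). Naive and circulating genes had a median of 0.24 (percentile 99.8) with 1 of 8 above, Ccr7 (25.6 against 15.4 CPM). Exhaustion and checkpoint genes had 0.24 (percentile 99.2) with 0 of 5 beyond, and Pdcd1 stood at 71.2 against 48.1 CPM. Sulfated glycosaminoglycan genes had -0.31 (percentile 0.08, 0 of 7 beyond), with the sulfatase Arsb at 433.5 against 607.4 CPM. The rest had medians of -0.01 for immediate-early and heat-shock genes (percentile 30.0, 1 of 13 below, Atf3), -0.04 for the cell cycle (percentile 16.7, 0 of 14 beyond) and -0.10 for the unfolded protein response (percentile 8.84, 0 of 9 beyond). Oxidative phosphorylation genes had -0.08 (percentile 2.41, 0 of 15 beyond), which was 0.00968 with cells thinned to 3000 UMIs. Of cholesterol synthesis fewer than 3 genes were measured, among them Sc5d at 24.2 against 21.4 CPM.

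Leading T/NK genes higher in Gel50_CS50 were Nckap5 (1.38), Cd163l1 (1.18), Neb (1.14), Prickle1 (1.14), Areg (215.5 against 100.4 CPM, 1.10), Abi3bp (1.10), the insulin-like growth factor receptor Igf1r (0.98), the costimulatory receptor Tnfrsf4 (0.95), Rab11fip1 (0.93) and Prickle2 (0.92). With the same cluster weights Nckap5 stood at 0.69, Cd163l1 at 0.47, Neb at 0.53, Prickle1 at 0.54 and Areg at 0.56. Abi3bp stood at 0.42, Igf1r at 0.44, Tnfrsf4 at 0.20, Rab11fip1 at 0.65 and Prickle2 at 0.23. Lower were the granzyme gene Gzmd (21.7 against 144.1 CPM, -2.73), Spp1 (58.1 against 362.5 CPM, -2.64, and -1.40 with doublet calls kept), Ms4a4c (-1.46), Plac8 (201 against 475.3 CPM, -1.24), Ifi44 (-1.24) and Ifitm1 (-1.21), and Hist1h2ap (-1.78) and Ly6c1 (-1.37), which have close copies. Cd74, the MHC class II chaperone, stood at 28.0 against 76.2 CPM (-1.45), far under its 8833 CPM in the conventional dendritic cells of Gel100, and at 0.24 with doublet calls kept.

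**Figure D3:**
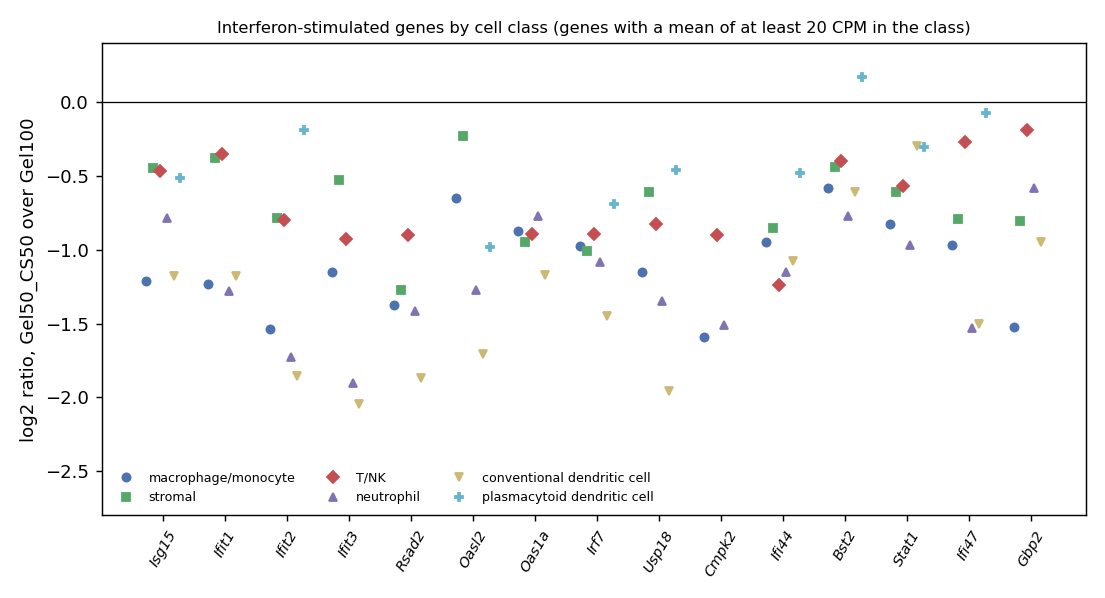
Log2 ratio of Gel50_CS50 over Gel100 (vertical axis) for the genes of the interferon list (horizontal axis) in 6 cell classes, each point a gene with a mean of at least 20 CPM in the class; counting intervals are not drawn. In the macrophage/monocyte class Rsad2 stood at -1.37 and Ifit2 at -1.54, and in stromal cells Rsad2 stood at -1.27.

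The other classes with at least 100 cells in each library were neutrophils, conventional and plasmacytoid dendritic cells. In neutrophils, genes of the granule and early maturation list were lower in Gel50_CS50, with 8 of 11 below 1/1.5 and 1 above, and a median of -1.63 (percentile 0). The antimicrobial peptide gene Camp stood at 341.3 against 2163 CPM (-2.66, -2.73 to -2.59), Ngp at 546.2 against 2743 (-2.33) and lactoferrin, Ltf, at 198.3 against 931.1 (-2.23). Ly6g, also on the list, stood at 62.7 against 287.1 (-2.19). Golim4, which is not on the list, was lower too, at 21.6 against 100.6 (-2.22). Tissue inflammatory genes had 5 of 14 above and 2 below, with a median of 0.41 (percentile 99.8), among them the chemokine genes Ccl3 (4814 against 2533 CPM) and Cxcl3 (182.5 against 85.5 CPM) and the lipopolysaccharide receptor Cd14 (1731 against 962.2 CPM). Camp (ENSMUSG00000038357) lies on chromosome 9 at 109847379 to 109849617. Cluster 25 held 10.1% of the neutrophils in Gel100 and 3.35% in Gel50_CS50, and with the same cluster weights the granule median was -0.25 and Camp stood at -1.03, Ngp at -0.68, Ltf at -0.69, Golim4 at -1.19 and Ly6g at -0.95. With the stricter cell filter Camp stood at -1.31, Ngp at -1.28 and Ltf at -1.59.

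Also higher in the Gel50_CS50 neutrophils were Saa3 (797.3 against 147.2 CPM, 2.44), the adenosine receptor Adora2a (113.7 against 22.9 CPM, 2.31) and the macrophage marker Adgre1 (473.8 against 101.7 CPM, 2.22, and 1.28 with doublet calls kept), which stood at 799.9 CPM in the macrophages of that library. The collagen genes Col3a1 (134.7 against 36.3 CPM, 1.89) and Col1a2 (110.7 against 32.2 CPM, 1.78) stood at 15880 and 14130 CPM in its stromal cells. Col3a1 was higher in T/NK cells as well, at 68.7 against 22.5 CPM. In conventional dendritic cells, Fn1 (130.5 against 17.5 CPM, 2.90, and 1.497 with each cell weighted equally), the chemokine genes Cxcl1 (142.9 against 24.6 CPM, 2.54) and Ccl17 (210 against 69.0 CPM, 1.60), the OX40 ligand Tnfsf4 (1.76) and Ifitm1 (1.67) were higher. Lower there were Ly6c2 (-3.33), a monocyte marker, the neutrophil markers S100a8 (16.4 against 116.2 CPM, -2.82) and S100a9 (-2.55), Ly6a (-2.46) and Slfn1 (-2.03). With doublet calls kept, Ly6c2 stood at -1.68, S100a8 at -1.69, S100a9 at -1.45, Slfn1 at -1.31 and Cxcl1 at 1.69. In plasmacytoid dendritic cells, the neutrophil markers S100a8 (140.1 against 7.15 CPM, 4.29) and S100a9 (4.02) were higher, at 2.43 and 1.97 with doublet calls kept, as were the activity-regulated receptors Nr4a1 (1.28) and Nr4a3 (218.1 against 92.0 CPM) and the phosphodiesterase Pde4b (1.17). Ms4a4c (-1.18, and -0.51 with doublet calls kept), Ly6a (-1.11), the histone deacetylase Hdac9 (-1.02) and the interferon-induced Oasl2 (-0.98) were lower.

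Levels of paired ligands and receptors were asked because the series title names crosstalk. These levels are relative to all counts of a class, and class sizes differed between the libraries. A lower level therefore need not mean fewer counts summed over the class. Stromal Ccl2 had 14389 summed counts in Gel50_CS50 and 8949 in Gel100, whereas macrophage Ccl2 had 25564 and 45214. Summed counts also depend on the total UMIs of a library, which were higher in Gel50_CS50. The monocyte chemokine Ccl2 was lower in Gel50_CS50 in macrophages and in stromal cells, as given above, and Ccl7 in macrophages (263.6 against 532.1 CPM). Their receptor Ccr2 stood at 327.7 against 345 CPM in macrophages and 485.1 against 464.8 in T and NK cells. Spp1 was higher in macrophages (0.92, 0.90 to 0.93), while its receptor Cd44 was lower in stromal cells. Fn1 was higher in macrophages, and its receptor subunit Itga5 stood at 101.2 against 147.8 CPM in stromal cells. Gas6 was higher in macrophages (1.11), while its receptor Axl stood at 171.9 against 253 CPM in stromal cells and 45.4 against 79.7 in macrophages. Areg was higher in macrophages (1.65) and in T and NK cells, in the latter at 0.56 with the same cluster weights. Its receptor Egfr stood at 406.4 against 309.6 CPM in stromal cells.

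Among ligands of T and NK cells, Ifng was lower, with its receptor Ifngr1 at 162.3 against 130.3 CPM in macrophages. Its summed counts were lower too, at 332 against 1217. Il17a was higher relative to all counts of the class, with Il17ra at 179 against 190.9 CPM in neutrophils. Its summed counts were nearly equal, at 271 in Gel50_CS50 and 269 in Gel100. Stromal Cxcl12 was higher (0.73, 0.66 to 0.81), and its receptor Cxcr4 stood at 131 against 307 CPM in neutrophils. Stromal Thbs1, a matricellular ligand of Cd47, stood at 146.1 against 88.7 CPM. Stromal Vegfa, the main endothelial growth factor, stood at 60.1 against 101 CPM (-0.75, -0.85 to -0.64), and Hbegf, an EGF receptor ligand, at 11.3 against 30.9 CPM. The summed stromal counts of Vegfa went the other way, at 2245 in Gel50_CS50 against 1119 in Gel100. Csf1, the growth factor of macrophages, stood at 969.5 against 1533 CPM in neutrophils, with its receptor Csf1r at 423.4 against 368.8 CPM in macrophages. Summed over neutrophils, Csf1 had more counts in Gel50_CS50, at 6386 against 4143. The anti-inflammatory cytokine gene Il10 stood at 70.0 against 30.0 CPM in neutrophils.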

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

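Among the named genes, 3 had intervals wholly above 1.5-fold in a main cell class and wholly below 1/1.5 in another, with a mean of at least 50 CPM in both classes. Mmp13, Il1rl1 and Pparg also had ratios beyond 1.5-fold in opposite directions, but did not meet the limits on the mean or the interval in both classes. The difference between classes was not tested, since each group has 1 library, and no explanation is offered for it.

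Spp1 had a log2 ratio of Gel50_CS50 over Gel100 of 0.92 in macrophages and -2.64 in T and NK cells, a gap of 3.56, and in T and NK cells it stood at -1.40 with doublet calls kept. Ifitm1 stood at 1.44 in macrophages and -1.21 in T and NK cells, a gap of 2.65. Cd74 stood at 0.77 in stromal cells and -1.45 in T and NK cells, a gap of 2.21, and in T and NK cells it stood at 0.24 with doublet calls kept.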

How the results depend on the processing

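Low-UMI and macrophage-cluster alternatives, the set with at least 3000 UMIs and the addition of mixed cluster 18 were chosen after seeing the data. Of 49 alternative values of class share differences, 45 kept their direction, as did 427 of 460 list medians and 649 of 650 named gene ratios. Of the 33 list medians that did not, 7 belong to lists outside the central 95% of random lists and are given below, and the others to lists within it. No paired analysis was possible because each group has 1 library and no test was run. The higher neutrophil and stromal shares and the lower T/NK and dendritic cell shares of Gel50_CS50, and the lower interferon list in all 3 main classes, held their direction under every alternative run. Assigning the low-UMI clusters could not change the neutrophil, stromal or conventional dendritic cell shares, since none of these clusters scored highest for those classes. Scaling shifted all genes of a class by at most 0.095 (log2), in neutrophils. The 35 ligand ratios were recomputed with TMM factors only, which shifted a class by at most 0.079. All 35 kept their direction, but they had been picked for lying beyond 1.5-fold, so this shift could not turn them. For the same reason neither scaling could turn a named gene. The cause of the moves below was not tested. The depth gap limits the shares, as 13.03% of Gel100 cells sat in low-UMI clusters.

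In percentage points, Gel50_CS50 minus Gel100, the macrophage difference reversed to -3.15 with the stricter filter, -7.42 with low-UMI clusters assigned and -5.01 with at least 3000 UMIs. Without clusters 6 and 11 it was -7.22. That fall was bound to follow, since cluster 11 held 58 cells of Gel100 and 602 of Gel50_CS50, so it does not bear on the macrophage share. The neutrophil difference was 9.93 with at least 3000 UMIs. The stromal difference was 6.71 with doublet calls kept and 7.07 with each library clustered alone. The T/NK difference was -7.84 with the stricter filter, -7.70 with doublets kept, -7.41 at Leiden resolution 0.5, -7.41 with low-UMI clusters assigned and -7.80 with at least 3000 UMIs. That of conventional dendritic cells was -0.48 at resolution 0.5, -0.34 with 50 principal components and -3.80 with libraries clustered alone, and its interval held 0 at resolutions 0.5 and 2.0 and with 50 components. That of plasmacytoid dendritic cells was -2.803 with the stricter filter, -3.12 with doublets kept, -2.63 at resolutions 0.5 and 2.0 and with low-UMI clusters assigned, -2.73 with libraries clustered alone and -2.93 with at least 3000 UMIs.

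With the same cluster weights in both libraries, the log2 medians were -0.34 for interferon genes in macrophages, 0.14 for regulatory T, 0.21 for type 2 and 0.034 for type 17 genes, and circulating monocyte genes reversed to 0.033. The clusters rest partly on the genes compared, so these weights can also remove a difference within a cell type. With each cell weighted equally, interferon genes in stromal cells stood at -1.06, fibrillar matrix genes at 0.26 and type 17 genes at 0.45. At a mean of at least 100 CPM, resident-type and complement genes reversed to -0.12, circulating monocyte genes to 0.39 and T/NK oxidative phosphorylation genes to 0.00836, the last also to 0.00968 with thinned cells. Lipid-associated genes reversed to -0.048 without clusters 6 and 11, stromal growth and angiogenic factors to -0.030 with no limit on CPM, and Cd74 in T and NK cells to 0.24 with doublets kept.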

Other observations

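The tests of UMIs per cell, of a gain of neutrophils alone and of the neutrophil genes were chosen only after the result was seen, and so were the genes named next. Of 2548 genes measured in all 6 compared classes, the following were picked from those with the widest margins on 1 side in every class, and no gene group was tested on them. Lower in Gel50_CS50 was B2m, the light chain of MHC class I, with log2 ratios from -0.43 in T and NK cells to -0.73 in stromal cells. The peptide transporter Tap1 stood between -0.40 in plasmacytoid dendritic cells and -0.95 in macrophages, and the class I gene H2-T22, which has close copies, between -0.39 in T and NK cells and -1.41 in macrophages. The interferon-inducible GTPase gene Irgm1 stood between -0.54 and -1.48 and the nucleic acid sensor Zbp1 between -0.49 and -1.21. The proteoglycan gene Sdc3 stood between -0.54 and -1.15, and Lgals3bp, which encodes a secreted glycoprotein, between -0.55 and -1.08. Higher in each class were Wfdc17, a protease inhibitor gene (0.25 to 1.40), the neutrophil chemokine gene Cxcl2 (0.24 to 1.55) and Tnip1, an inhibitor of NF-kB signalling (0.18 to 1.18). Col1a2 was higher in each as well (0.22 to 2.10), although it is a stromal gene.

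Interferon-stimulated genes were lower in the Gel50_CS50 library in the 3 main classes. Macrophage RNA in the droplets of other cells was argued against as the whole cause: after its subtraction the median was -0.58 in stromal and -0.57 in T and NK cells. With cells thinned to 3000 UMIs the highest of the 3 medians was -0.82. The lower list therefore did not rest on the unequal weight of cells or on cells under 3000 UMIs. Thinning keeps the expected gene proportions of each cell, so it cannot decide on other effects of a difference in UMIs per cell. Scaffold composition remains open as an explanation, and a difference between the 2 pools or preparations cannot be told apart from it with 1 library per group.

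Neutrophil and stromal shares were higher and the T/NK share lower in the Gel50_CS50 library. Dilution by low-UMI barcodes in Gel100 was argued against as the whole cause by its size. Low-UMI clusters held 13.03% of Gel100, too small a part to give share ratios of 2.40 for neutrophils and 2.86 for stromal cells. Among cells with at least 3000 UMIs the smaller of these ratios was 2.13. For the same reason it was bound to stay high, and it adds no separate evidence. A gain of neutrophils alone was argued against as well. Per macrophage, stromal cells were 2.77 times as many and T and NK cells 1.89 times fewer in Gel50_CS50, where dilution would move both alike. Scaffold composition stays open and cannot be told apart from differences in digestion or sorting with 1 library per group.

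Stromal and macrophage genes were higher in the Gel50_CS50 neutrophils. For the stromal genes, free stromal RNA and doublets with stromal cells are candidate sources. In Gel50_CS50, 8 fibroblast markers stood at 0.783 to 1.55% of their stromal level, within 1.98-fold of each other. Either source would give such even ratios, so these values cannot tell them apart. For Adgre1 and Saa3, free RNA or doublets of macrophages with the average profile of the class were argued against. These genes stood at 13.7 and 9.13 times the level that 10 other macrophage markers give. With doublet calls kept their log2 ratios were 1.28 and 2.07, against 2.22 and 2.44. RNA or doublets of a macrophage subset with another profile were not tested. Cluster 12, with Saa3 among its leading genes, held 179 cells in Gel100 and 456 in Gel50_CS50. Eosinophils, which also express Adgre1, were argued against by 6 of their markers, which came to 7.59 CPM together. What raises Adgre1 and Saa3 in this class stays open, scaffold composition included, which was not tested.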
